A study of Mus musculus with 6 samples.

How the data were processed

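Total RNA of 6 heart samples, 3 given the miR-433 antagomir and 3 the scrambled control, was measured on 1-colour Agilent arrays with Cy3. Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 10.7.1.1. They hold the processed signal of each spot as an intensity, corrected for background and detrended within the array by that software, and not normalised between arrays. The mean signals and local backgrounds in the deposited files are intensities too, and the remaining columns used here are other values, per the file headers 0 or 1 for each spot. The authors' deposited table holds raw columns, which are intensities equal to the scanner's processed signal (within 1% for 99.99% of probes or more), and normalised columns in log2 units, whose sorted values are the same in every column to within 0.00143, as quantile normalisation gives. The labels state no method for it.

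Each array had 62976 spots, of which 59305 were for genes. Control spots and spots marked as outliers by the scanner software (154 to 233 per array) were left out, and spots of 1 probe were averaged on the log2 scale, giving 55681 probes, of which 20 had no usable spot on some array and were left out. Probe positions are those of the array design (mm9). Names were brought up to date with a table of mouse genes (GRCm38.p6), used for names and neighbours only: 26582 probes were named by RefSeq accession, 2602 had a current symbol, 492 were renamed through a synonym and 26005 kept the name in the file. Values are log2 of the processed signal minus the array's 75th percentile. Probes well above background on at least 3 of the 6 arrays, whatever their group, were tested (31716), and the probe with the highest mean over all arrays stood for its gene (22991 genes). Depth on arrays is signal over background: the share of gene spots well above background was 58.3%, 58.5% and 57.7% on control arrays 1 to 3 and 55.2%, 56.2% and 73.6% on antagomir arrays 1 to 3, and 0 spots were saturated. Where no array of a group was well above background, the fold is given as a lower bound against the lowest signal called above background.

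Groups were compared with limma 3.58.1 in R 4.3.3 (a linear model with moderated variances, two-sided, with Benjamini-Hochberg adjusted p under 0.05). Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. A test of 3 against 3 by permutation cannot give a p below 0.1. Gene lists, 43 in all, and the comparisons and most of the other settings were fixed before the data were examined. The 41 lists with at least 5 genes tested were compared with all other genes by camera with a preset correlation of 0.01, adjusted over those lists, and again with an estimated correlation and with fry, which tests a list by itself. Of 22 lists past camera's threshold, 8 higher and 14 lower, 0 passed with an estimated correlation (4 at an unadjusted p under 0.05) and 0 by fry (7 at an unadjusted p under 0.05, and 2 past the threshold when either direction counts). Other splits of the arrays into 3 and 3 put 12 to 21 lists past camera's threshold. Signs of median and test differ for the polyamine, interferon, immediate early and unfolded protein lists, none of which passed. The mean differs in sign from the median for the polyamine, immediate early, skeletal muscle and oxidative stress lists, which did not pass either.

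Genes are named by this rule: Azin1 and Mapk8; among genes with a symbol past the adjusted threshold and without overlap, the 12 largest in each direction, filled up by the smallest unadjusted p among those of at least 1.5-fold; and up to 4 members with the smallest p of each list that passed or that concerns fibrosis, targets, macrophages or the sarcomere. Genes from outside it are said to be chosen after their values were seen. Of 121 genes so named, 28 had more than 1 tested probe, and in 0 of these did the probes differ in sign. On simulated data with 200 changed genes in each of 5 runs, the same steps called 23.2% of genes changed 2-fold, 64.4% at 4-fold, 79.2% at 8-fold and 86.8% at 16-fold, with 40 false calls over all runs. They found the changed list in 5 of 5 and called 1 other list over all runs. Genes were simulated independently, whereas the estimated correlation within the matrix list was 0.479 on the real arrays. False calls of genes or lists on the real arrays cannot be judged from it. Alternatives were normexp background correction with an offset of 50 and quantile scaling, quantile scaling alone, scaling by the median, the authors' table, no filter and 2 stricter filters, the mean of a gene's probes, every probe by itself, a variance trend with robust moderation, array weights, replicate number as a block, an equal-variance test, other thresholds and each array left out in turn. The slide row as a block and a mean signal of at least 200 were added after the data were seen. Control arrays 1 and 2 are alone in row 1, so that block compares control array 3 by itself with the antagomir arrays. The slide could not serve as a block, since there was 1. Genes with a miR-433 seed site were not analysed here, because no 3' UTR sequences were at hand.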

Results

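The series measured RNA in hearts of male C57BL/6 mice 21 days after myocardial infarction, made by ligating the left anterior descending coronary artery. The mice had received 80 mg/kg of a miR-433 antagomir, an oligonucleotide that blocks this microRNA, or a scrambled control by tail vein on 3 consecutive days. Each group had 3 samples, hybridised to 1-colour Cy3 arrays, and the question was whether blocking miR-433 limits cardiac fibrosis. The labels do not say whether each array holds RNA of a separate mouse, so the p-values measure spread between these samples only. They do not say either which part of the heart was taken. All 6 arrays lay on 1 slide and were read in 1 scan. Between 57.7% and 58.5% of gene spots were well above background on the control arrays, against 55.2%, 56.2% and 73.6% on antagomir arrays 1, 2 and 3. Correlations between arrays, taken across genes, which are not independent replicates, ran from 0.953 to 0.992. Antagomir array 3 stood apart at its dim end: among probes dim on the other 5 arrays, 85.3% of those rich in purines (A and G) were well above background on it, against 3.92% of those poor in purines. On the other arrays the purine-rich share was between 0.885% and 3.66%, among probes that had to be dim on antagomir array 3. Fold changes below are antagomir minus control on the log2 scale, levels are log2 signals minus the array's 75th percentile, and n = 3 per group throughout. With this scaling 14401 of 22991 genes tested were higher and 8590 lower. The number of arrays limits the precision.

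**Figure D1:**
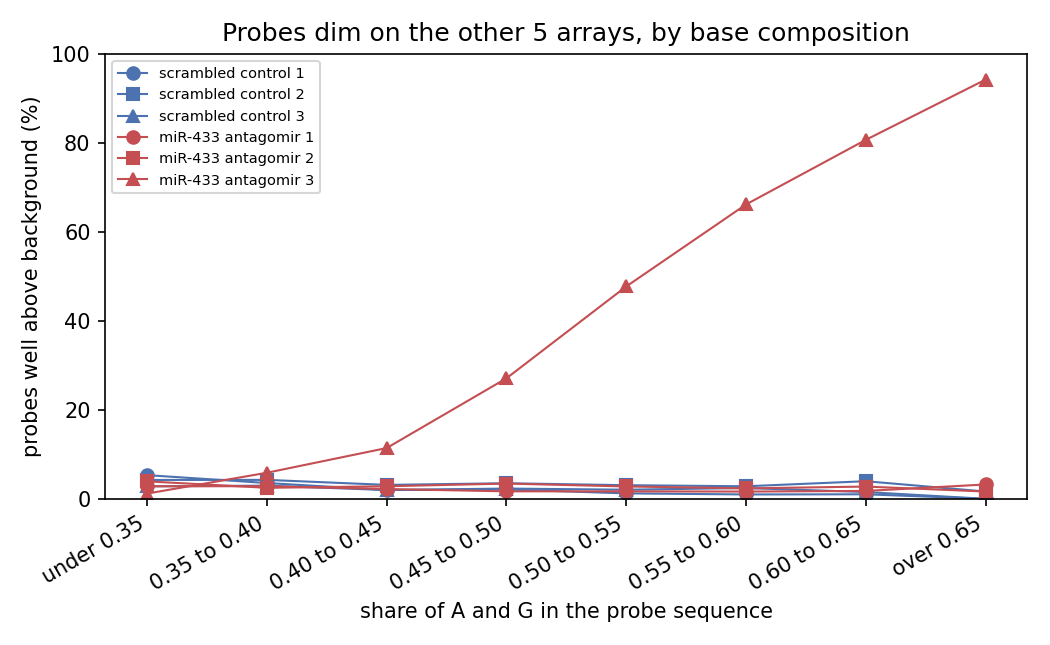
Percent of gene probes well above background (vertical axis) by the share of A and G in the probe sequence (horizontal axis), for probes dim on the other 5 arrays; each line is 1 array, blue for scrambled control and red for miR-433 antagomir. Antagomir array 3 goes from 1.18% in the lowest bin to 94.2% in the highest. The other arrays, whose probes had to be dim on antagomir array 3, are at most at 5.32% in any bin.

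Matrix genes were lower in the hearts given the antagomir. Of 39 collagens and structural matrix genes tested, 38 were lower and 1 higher, with a median of −1.63, a 3.10-fold difference (−1.59 with 2 members at background in a whole group set to their bound). The mean level of the list was −1.97 ± 0.39 (SD) on the antagomir arrays against a control mean set to 0 ± 0.62, and every antagomir array lay below every control array. Adjusted over the list alone, 35 of the 39 passed, all lower, and 27 to 33 passed with 1 array left out. Over all genes tested 0 passed with limma (35 had an unadjusted p under 0.05). Col3a1, the chain of type III collagen, had a level of 7.05 ± 0.44 in controls and 3.72 ± 1.01 with the antagomir (log2 fold change −3.33, SE 0.53, limma adjusted p = 0.497). Col6a1 (−1.63, SE 0.25) and Eln, which encodes elastin (−1.79, SE 0.29), did not overlap between groups either. Col1a1, chosen after its values were seen, had a fold change of −2.82 (SE 0.50). The list fell by camera (adjusted p = 3.38e-40 with a preset correlation of 0.01), with adjusted p = 0.369 with an estimated correlation. With the slide row as a block the fit left control array 3 alone against the antagomir arrays, since row 1 holds control arrays alone. It cannot decide whether the slide row plays a part in this list.

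**Figure D2:**
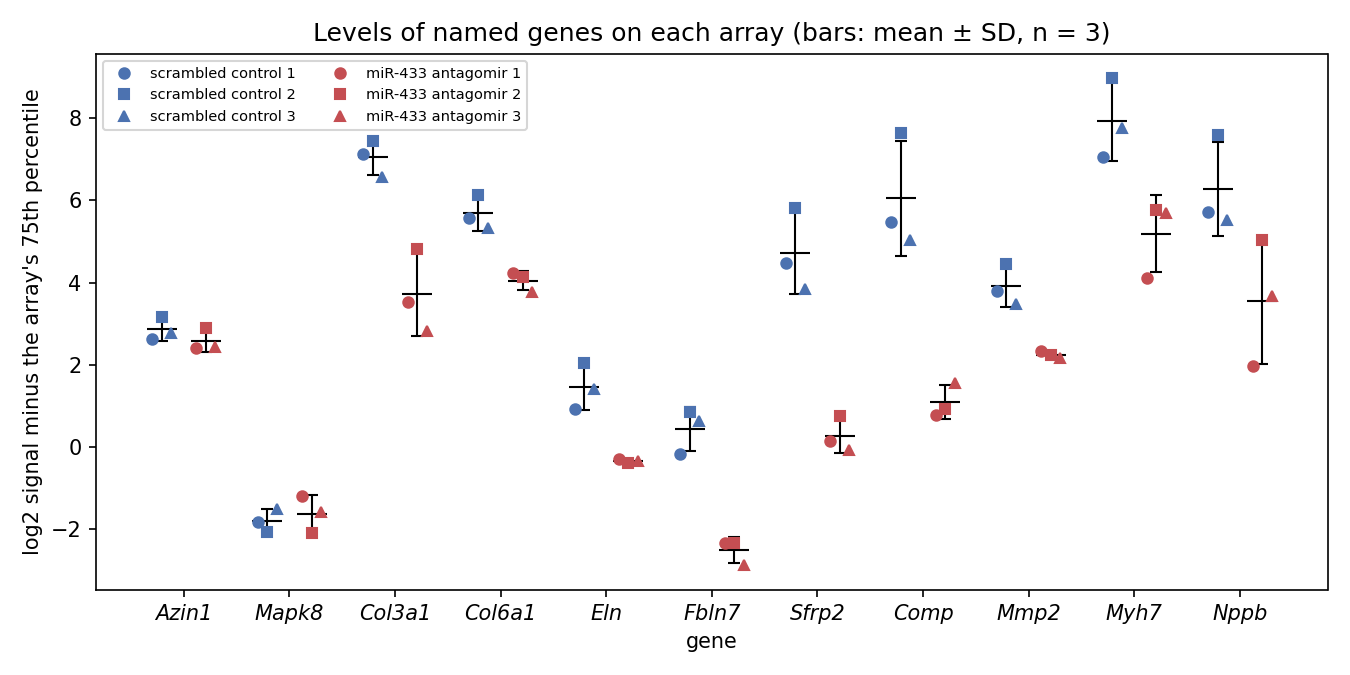
Level of each named gene on each array (log2 signal minus the array's 75th percentile, vertical axis), blue for scrambled control and red for miR-433 antagomir; symbols mark the replicates and bars give the mean ± SD, n = 3. Azin1 and Mapk8 overlap between the groups, while Col3a1 goes from a mean of 7.05 in controls to 3.72 with the antagomir.

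Genes of the fibroblast state went the same way. All 25 myofibroblast activation genes were lower (median −1.37), and 17 passed adjusted over the list alone, with 0 over all genes by limma and 17 at an unadjusted p under 0.05. Comp, cartilage oligomeric matrix protein, had a log2 fold change of −4.96 (SE 0.69), and Sfrp2, a secreted Wnt modulator, of −4.44 (SE 0.52). Cthrc1, a collagen triple helix repeat protein, was well above background on all 3 control arrays and on 0 of 3 antagomir arrays, at least 18.2-fold lower. Postn (periostin), chosen after its values were seen, had a fold change of −3.71 (SE 0.66), and Acta2, smooth muscle actin, also so chosen, of −0.34 (SE 0.22). Of 28 matrix crosslinking and turnover enzymes 23 were lower (median −0.78), among them the proteases Mmp2 (−1.66, SE 0.26), Mmp14 (−0.78, SE 0.16) and Mmp3 (−1.17, SE 0.27) and the lysyl oxidase Loxl1 (−1.48, SE 0.33), and 10 passed adjusted over the list alone. Markers of resting fibroblasts were lower for 14 of 17 (median −0.55), 4 of them passing adjusted over the list alone, with Smoc2 at −0.68 (SE 0.16), Mfap5 at −1.96 (SE 0.50) and Pi16 at −1.56 (SE 0.42). Over all genes 0 of either list passed by limma, with 13 enzymes and 7 resting markers at an unadjusted p under 0.05. The myofibroblast, enzyme and resting fibroblast lists fell by camera, with adjusted p = 3.74e-24, 4.01e-13 and 1.51e-07 in that order, and adjusted p = 0.369 with an estimated correlation for each. With the slide row as a block the myofibroblast median was −0.80.

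TGF-beta and Wnt signalling genes and markers of cartilage and bone were lower. Of 32 TGF-beta and Smad genes, 24 were lower (median −0.29), 0 passed adjusted over the list alone or over all genes by limma, and 8 had an unadjusted p under 0.05. Tgfb3 (−1.58, SE 0.34), Tgfb2 (−1.45, SE 0.48), the activin subunit Inhba (−1.55, SE 0.41) and Ltbp3, a latent TGF-beta binding protein (−1.08, SE 0.26), were members with low p-values. Tgfb1, chosen after its values were seen, had a fold change of 0.03 (SE 0.16). Of 28 Wnt genes 18 were lower and 10 higher (median −0.22), with 4 lower ones passing adjusted over the list alone: Sfrp2, Frzb (−2.77, SE 0.59), Sfrp4 (−2.20, SE 0.50) and Sfrp1 (−1.51, SE 0.37), which encode secreted Wnt modulators. Sfrp5 of the same family, chosen after its values were seen, had a fold change of 3.09 (SE 0.93). Cartilage and bone markers were lower for 9 of 12 (median −0.70), 1 of them passing adjusted over the list alone, with Sox9, a chondrogenic transcription factor, at −1.89 (SE 0.58) and Mgp, matrix Gla protein, at −0.84 (SE 0.26). Over all genes 0 of these passed by limma, with 7 Wnt genes and 4 cartilage and bone markers at an unadjusted p under 0.05. The lists fell by camera, with adjusted p = 1.48e-07 for TGF-beta, 0.00133 for Wnt and 0.000255 for cartilage and bone, and adjusted p = 0.369 with an estimated correlation for each. Without control array 2, the median of the TGF-beta list was −0.16, that of Wnt −0.14 and that of cartilage and bone −0.44, which was −0.096 with no filter and −0.39 with array weights. With array weights the TGF-beta median was −0.14.

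Genes of the fetal and stretch-induced programme, which cardiomyocytes switch on under load, were lower for 12 of 17 (median −1.03). Adjusted over the list alone 3 passed, and 0 over all genes by limma, with 5 lower and 1 higher at an unadjusted p under 0.05. Relative to the control mean, the list's mean was −0.39, 0.67 and −0.28 on control arrays 1, 2 and 3. It was −1.61, −0.43 and −0.47 on antagomir arrays 1, 2 and 3, so the last 2 lay close to control arrays 1 and 3. Myh7, the slow myosin heavy chain, had a level of 7.93 ± 0.96 in controls and 5.19 ± 0.94 with the antagomir (log2 fold change −2.74, SE 0.64), and Nppb, the gene of B-type natriuretic peptide, had a fold change of −2.71 (SE 0.91). Cilp, which the list holds although fibroblasts are known to make it, had a fold change of −3.57 (SE 0.66). The list fell by camera (adjusted p = 0.000201), with adjusted p = 0.483 with an estimated correlation. Its median was −0.59 without antagomir array 1 and −0.38 with the slide row as a block.

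Genes of mitochondrial energy supply were higher together, by small amounts. All 49 oxidative phosphorylation genes were higher (median 0.33, a 1.26-fold difference), as were all 30 of fatty acid oxidation (median 0.49) and all 25 of the citric acid cycle and mitochondrial biogenesis (median 0.35). With quantile scaling, which moves the median of all genes from 0.09 to −0.03, 47, 29 and 25 members were higher, and the medians were 0.12, 0.32 and 0.17. Cox5a, a subunit of cytochrome c oxidase, had a log2 fold change of 0.38 (SE 0.14), Ndufa4 of 0.42 (SE 0.18), Decr1, an enzyme of unsaturated fatty acid oxidation, of 0.64 (SE 0.26), Pdk4, a brake on pyruvate oxidation, of 0.72 (SE 0.33), and Cs, citrate synthase, of 0.34 (SE 0.17). Adjusted over each list alone 0 genes passed, as over all genes by limma, and 1, 0 and 0 had an unadjusted p under 0.05. The lists rose by camera, with adjusted p = 2.66e-09, 1.62e-06 and 0.000157, and adjusted p = 0.625, 0.625 and 0.660 with an estimated correlation. Without control array 2 the medians were 0.18, 0.20 and 0.16. With the slide row as a block, which leaves a single control array against the antagomir arrays, the medians were 0.12, 0.13 and 0.13. That fit cannot decide whether the slide row plays a part in these lists.

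Calcium handling and ion channel genes were higher for 23 of 26 (median 0.40), 0 of them passing adjusted over the list alone or over all genes by limma, with 1 at an unadjusted p under 0.05. Atp2a2, the calcium pump of the sarcoplasmic reticulum, had a log2 fold change of 0.31 (SE 0.14), and Adrb1, the beta-1 adrenergic receptor, of 0.59 (SE 0.21). Sln (sarcolipin), an atrial inhibitor of that pump, had a fold change of 5.30 (SE 2.29), with signals of 27.3, 104 and 608 in controls and 131, 12445 and 39411 on antagomir arrays 1, 2 and 3. Of 23 sarcomere genes 22 were higher (median 0.19), but 14 were lower with quantile scaling (median −0.028). Myoz2 (0.38, SE 0.16) and Tnni3, cardiac troponin I (0.35, SE 0.16), were among the higher ones, and Myh7 was the 1 lower. Adjusted over the list alone, and over all genes, 0 sarcomere genes passed by limma, and 1 had an unadjusted p under 0.05. The calcium list rose by camera (adjusted p = 0.00128) and the sarcomere list too (adjusted p = 0.0129), both with adjusted p = 0.625 with an estimated correlation. The calcium median was 0.19 without control array 2, and 0.13 with the slide row as a block, which leaves control array 3 alone against the antagomir arrays. The sarcomere call was lost without antagomir array 1 (median 0.17, adjusted p = 0.0651), with no filter (adjusted p = 0.271) and with every probe on its own (0.16 and 0.0565). Its median was 0.11 with the slide row as a block.

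Endothelial, smooth muscle, macrophage, complement and cytokine lists were lower. Of 30 endothelial markers 21 were lower (median −0.09), with Erg, an endothelial transcription factor, at −0.61 (SE 0.17) and Plvap at −1.39 (SE 0.39), and of 17 smooth muscle and pericyte markers 12 were lower (median −0.28), with Pdgfrb at −0.64 (SE 0.18), Tagln at −1.11 (SE 0.34) and Cnn1 at −1.30 (SE 0.43). Of 32 macrophage and monocyte markers 23 were lower (median −0.23), with Gpnmb at −1.94 (SE 0.40), Spp1 (osteopontin) at −3.57 (SE 1.20) and Trem2 at −1.25 (SE 0.49), all linked to scar-associated macrophages, and Cd163, a marker of resident macrophages, at 0.82 (SE 0.38, 0.42 without control array 2). These were the members with the smallest unadjusted limma p, above 0.05 for Cd163. A difference between kinds of macrophage was not tested. Complement and coagulation genes were lower for 21 of 28 (median −0.20), with C6, of the terminal complement pathway, at 1.57 (SE 0.35). Inflammatory cytokines and chemokines were lower for 17 of 31 (median −0.10), with Il11 at −1.37 (SE 0.43) and Il33 at −1.50 (SE 0.48). Adjusted over each of these lists alone 0 genes passed, as over all genes by limma, with 5, 6, 3, 5 and 3 at an unadjusted p under 0.05. All 5 lists fell by camera, with adjusted p = 0.00144, 0.00194, 0.0111, 0.00409 and 0.0442, and adjusted p = 0.483, 0.369, 0.734, 0.625 and 0.660 with an estimated correlation. Without antagomir array 3 the macrophage median was 0.10 (adjusted p = 0.778), the complement median 0.02 (adjusted p = 0.633) and the cytokine median 0.08 (adjusted p = 0.761). Without antagomir array 2 these medians were −0.65, −0.54 and −0.40, that of smooth muscle −0.083 (adjusted p = 0.0600) and that of endothelium −0.041. Without antagomir array 1 the macrophage median was −0.071 (adjusted p = 0.101), the complement median −0.11, the cytokine median −0.035 (adjusted p = 0.0531) and the endothelial median −0.14. Without control array 1 the smooth muscle median was −0.18 and the cytokine median 0.096 (adjusted p = 0.149), which without control array 2 was −0.16 (adjusted p = 0.105) and without control array 3 was −0.24. With quantile scaling the macrophage and cytokine calls were lost although the medians were larger in size (−0.29 with adjusted p = 0.0667, and −0.40 with adjusted p = 0.195), as with the authors' table (adjusted p = 0.0680 and 0.196). With the slide row as a block, which leaves control array 3 alone against the antagomir arrays, these medians were −0.14 and −0.10. The cytokine call was also lost above background on all 6 arrays (−0.048, adjusted p = 0.117) or on all 3 of a group (adjusted p = 0.0573), with normexp (−0.19, adjusted p = 0.263) and by the equal-variance test (adjusted p = 0.0731).

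**Figure D3:**
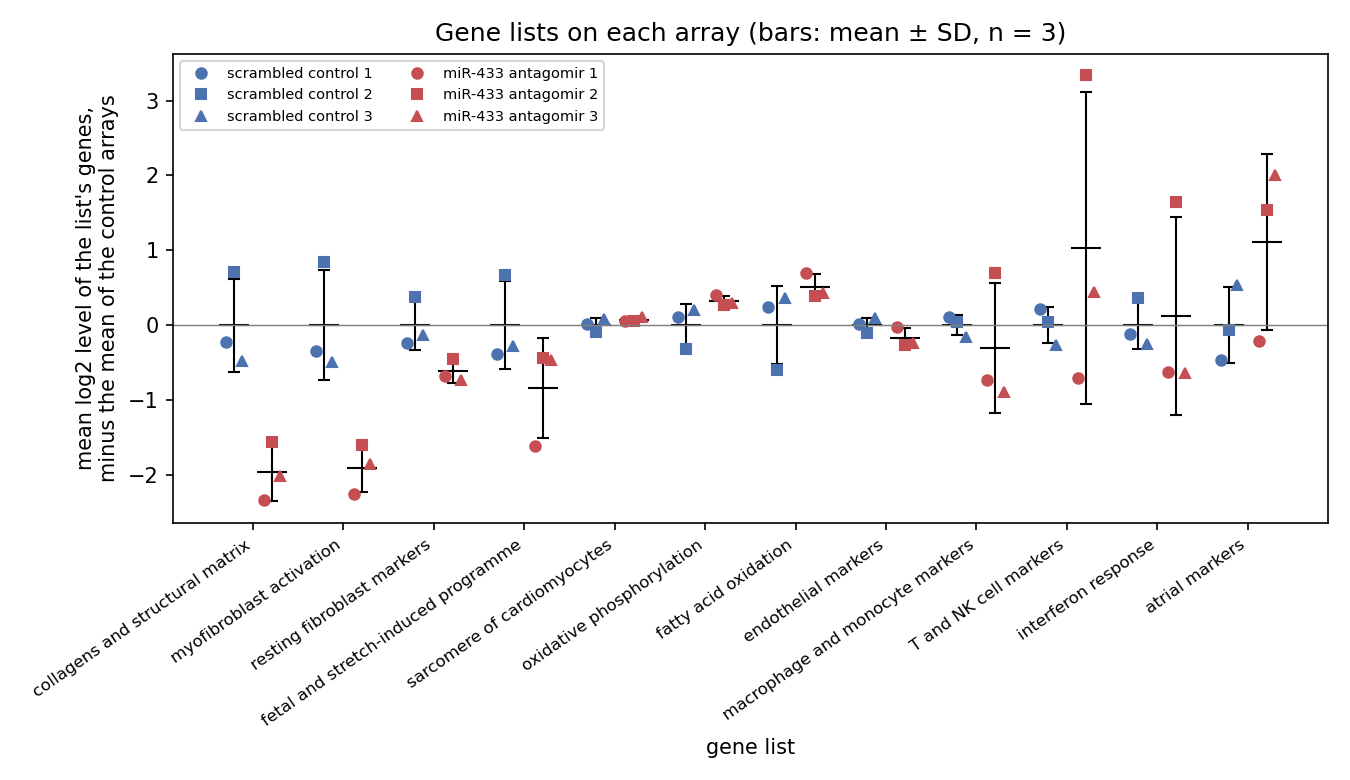
Mean log2 level of each gene list's members on each array, minus the mean of the control arrays (vertical axis), by list (horizontal axis); symbols mark the replicates and bars give the mean ± SD, n = 3. The matrix list sits at −1.97 ± 0.39 on the antagomir arrays, T and NK markers at 3.34 on antagomir array 2 alone, and the sarcomere list, positive here, has a median of −0.028 with quantile scaling.

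The named targets of miR-433 did not pass. Azin1 (antizyme inhibitor 1, probe on mm9 chromosome 15 from 38420056 to 38420115) had a level of 2.86 ± 0.27 in controls and 2.58 ± 0.27 with the antagomir, a log2 fold change of −0.28 (SE 0.22, limma adjusted p = 0.695), which was −0.13 without control array 2 and −0.44 without antagomir array 2. Direct targets of a blocked microRNA would be expected higher, but the arrays measure RNA and not protein. The 95% interval of the Azin1 value, −0.81 to 0.25, takes in a rise, so these values cannot decide whether it is a target. Azin1 was lower on its other probes too (−0.35 and −0.10), and its sign turned in 0 of 21 other settings. Mapk8, the gene of the stress kinase JNK1 (probe on chromosome 14 from 34191681 to 34191740), had levels of −1.79 ± 0.28 and −1.62 ± 0.44, a fold change of 0.17 (SE 0.27, limma adjusted p = 0.826). On its other probes Mapk8 was higher too (0.41, SE 0.33, and 0.44, SE 0.29). The sign of the value of the probe used turned without antagomir array 1 (−0.040) and with the slide row as a block (−0.11). Of 14 polyamine metabolism genes, the pathway Azin1 regulates, 7 were higher and 7 lower (median −0.031, mean 0.05, camera adjusted p = 0.916), with Agmat at 0.51 (SE 0.17) and Amd2 at 0.56 (SE 0.32, 0.24 without control array 2). MAP kinase genes were higher for 17 of 25 (median 0.13, from 0.052 without antagomir array 1 to 0.21 without antagomir array 2, camera adjusted p = 0.830), with Dusp6, a phosphatase of ERK, at −0.56 (SE 0.20) and Mapk13 at 0.77 (SE 0.29). Reported miR-433 targets were higher for 7 of 10 (median 0.09, camera adjusted p = 0.841). With quantile scaling 5 were higher and 5 lower, and the median was −0.017. Over all genes tested 14401 of 22991 were higher (median 0.09), near the shares of MAP kinases and reported targets. Adjusted over each of these lists alone 0 genes passed, as over all genes by limma, and 1, 2 and 0 had an unadjusted p under 0.05. Of the Dlk1-Dio3 locus, the imprinted region that holds miR-433, 4 genes were tested, too few for a list test, and 3 were lower. The non-coding Meg3 (−1.43, SE 0.41) and Begain (−1.78, SE 0.40) passed adjusted over the list alone, not over all genes. Genes with a miR-433 seed site were not analysed here.

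Gene by gene, 3 of 22991 genes passed limma's adjusted threshold of 0.05, all higher with the antagomir and all at the dim end. Defa-ps1, a defensin pseudogene (chromosome 8 from 22805553 to 22805612), was well above background on 3 of 3 antagomir arrays and on 0 of 3 controls, at least 11.8-fold higher (adjusted p = 0.00294, mean signal 3.22 in controls and 130 with the antagomir). Gngt1, a transducin subunit of rod photoreceptors (chromosome 6 from 3946662 to 3946721), was at least 4.26-fold higher (adjusted p = 0.0496), a call lost in 15 of 19 other settings, where that of Defa-ps1 was lost in 7 of 19. A probe for a long non-coding RNA on chromosome 6 from 40697866 to 40697925, chosen after its values were seen since it has no symbol, was at least 4.80-fold higher (adjusted p = 0.0349). These bounds hold for the processed signals: with normexp and quantile scaling, where an offset of 50 is added to dim signals, the log2 fold change was 1.42 for Defa-ps1 (adjusted p = 0.0614) and 0.69 for Gngt1 (adjusted p = 0.546). Without control array 1, 2 or 3 the count was 0 each time, and without antagomir array 1 or 3 it was 2. Without a control array the log2 difference of Defa-ps1 stayed between 5.47 and 5.62 (5.55 with all arrays). Its control signals lie at background, so these values are not measured folds. All 3 genes had control SDs of 0.074 to 0.15, which is spread of background signal and not of expression. Their p-values rest in part on that spread, so they do not measure differences in expression between hearts alone. At an unadjusted p under 0.05 there were 1658 genes, 702 higher and 956 lower, where 1150 would come by chance, and in 15.7% of genes the groups did not overlap, where chance gives 10%. With quantile scaling 25.3% of the genes at an unadjusted p under 0.05 were higher, against 42.3% here. Their number was 911 without control array 2 and 2743 with array weights. Those weights lean on control array 1 (5.91, against 0.37 to 1.65 for the other arrays).

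Other single genes did not pass the adjusted threshold with these settings. Those lower included Fbln7, a fibulin of the matrix (0.44 ± 0.54 in controls, −2.51 ± 0.31 with the antagomir, limma adjusted p = 0.20), Clca3a1 (−1.44, SE 0.17), Crabp2, which binds retinoic acid (−2.18, SE 0.29), the related growth factors Mdk (−1.91, SE 0.27) and Ptn (−3.07, SE 0.47), and Edn1, the gene of endothelin 1 (−0.91, SE 0.14). Those higher were mostly dim: Ttc9b (at least 3.16-fold), Nps (at least 2.87-fold), Ccl28 (at least 2.17-fold) and Spaca3 (at least 4.17-fold) were above background on 0 control arrays. With array weights Nps, Ttc9b and Ccl28 passed (adjusted p = 0.00922, 0.0108 and 0.0195), and Nps also without antagomir array 2 (adjusted p = 0.0290). The weighted fit leans on control array 1 (weight 5.91, others 0.37 to 1.65), where these genes lie at background. Clec4f, a lectin of Kupffer cells (2.18, SE 0.26), and Pvalb, the calcium buffer parvalbumin (1.16, SE 0.17), were above background on all 6.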

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

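Both tests in this part were chosen after the result was seen, and so was the multiple of 1.5 above the control arrays at which a control-spot signal is listed. Groups of 3 arrays are too small to test for outlying samples. Signals in spots with no mouse target, which the comparisons do not use, were above the level of the control arrays on antagomir array 3. The median processed signal of its negative control spots was 6.32, against 3.01 to 3.18 on the control arrays. The spike-in probe E1A_r60_3 had a signal of 33.8 against 3.22 to 3.81, and the spike-in probe E1A_r60_a104 of 75.6 against 3.21 to 4.44.

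The raised low end of antagomir array 3 was weighed against a technical and a biological source. More mouse transcripts expressed in this heart would leave the negative control spots at the level of the other arrays, and their signal of 6.32 argues against that as the whole cause. Labelled material binding without a specific target, by probe base composition, may be the source: across 20226 probes dim on the other 5 arrays, the excess signal correlated with the purine share at r = 0.65, against −0.20 to −0.08 on the other arrays. For the other arrays the probes had to be dim on antagomir array 3, which was also in their reference, so their values are no fair comparison. These correlations are across probes, which are not independent replicates. What in the sample or its labelling would make it so was not tested.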

How the results depend on the processing

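The slide row block and the mean signal of at least 200 were chosen after the data were seen. The slide as a block (there was 1 slide) and seed-site alternatives were not run. Signal over background limits the 3 genes past the threshold, whose control signals lie at background. Where no reason is given, the cause was not tested. Leaving the slide row block aside, the matrix list kept its direction and passed by camera with the preset correlation. Its median of −1.63 had an adjusted p of 0.369 with an estimated correlation and 0.137 with fry, and the number of lists was 0 with each. Matrix genes passing over the list alone numbered 27 to 33 with 1 array left out. That count did not hold with the slide row block, which leaves control array 3 alone against the antagomir arrays and decides nothing here.

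The number of genes changed was 0 with normexp, above background on all 6 arrays, replicate block, slide row block and mean signal of at least 200, 1 with quantile scaling, the authors' table, no filter and the equal-variance test, 6 with every probe on its own, 8 with array weights, 5 at an adjusted p under 0.10 and 594 at an unadjusted p with at least 2-fold, and from 0 to 3 with 1 array left out. Genes at an unadjusted p under 0.05 numbered 2743 with array weights, 307 with the slide row block and 911 to 2468 with 1 array left out. The slide row block compares control array 3 alone with the antagomir arrays, so its counts decide nothing about an effect of the row. Array weights lean on control array 1 (5.91, against 0.37 to 1.65 for the other arrays), so the counts with them rest largely on that array among the controls.

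Signs turned as follows, in the order authors' table, normexp with quantile, quantile. Medians were −0.026, −0.022 and −0.028 for sarcomere, −0.066, −0.067 and −0.065 for ribosomal proteins, −0.0014, −0.0021 and −0.00063 for glycolysis, −0.018, −0.024 and −0.017 for immediate early genes, −0.018, −0.019 and −0.017 for reported miR-433 targets, and −0.071, −0.044 and −0.070 for the unfolded protein response. Without normexp, −0.18 and −0.18 held for lung markers and −0.27 and −0.27 for Cxcl10. With array weights values were −0.10 for interferon, −0.078 for neutrophils, −0.0068 for red blood cells, −0.077 for H2-K1 and −0.037 for Tgfb1. With the slide row block they were −0.11 for Mapk8, −0.028 for Tgfb1, 0.017 for Schwann cells, 0.021 for apoptosis, 0.092 for epicardial markers, −0.083 for reported targets, −0.035 for the unfolded protein response and 0.029 for polyamine genes. Other filters gave 0.059 for B cells (all 6 arrays), 0.24 for Schwann cells (no filter), and 0.13 (at least 200) and 0.13 (no filter) for cytokines. Polyamine medians were 0.0090 with all 3 arrays of a group, 0.0090 with all 6, 0.0065 with every probe, 0.0032 with the mean of probes, and 0.061 both with at least 200 and with no filter.

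With 1 array left out, ranges that cross 0 were −1.47 to 1.90 for Cxcl10, −0.49 to 0.89 for H2-K1, −0.040 to 0.40 for Mapk8, −0.051 to 0.12 for Tgfb1 and −0.29 to 3.27 for Gzma. For list medians they were −0.35 to 0.030 for Schwann cells, −0.60 to 0.35 for epicardial markers, −0.40 to 0.28 for immediate early genes, −0.40 to 0.096 for cytokines, −0.50 to 0.53 for interferon, −0.030 to 0.090 for polyamine genes, −0.10 to 1.48 for red blood cells, −0.0018 to 0.18 for reported targets, −0.061 to 0.19 for the unfolded protein response, −0.16 to 1.93 for T and NK cells, −0.54 to 0.020 for complement and −0.65 to 0.097 for macrophages.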

Other observations

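In this part the tests on the matrix genes were chosen after the result was seen, and those on the Ccl21-type genes after these genes were seen to be lower but before the values of the other genes they use. The splits were chosen before. Antagomir array 2 had the highest T and NK cell and interferon markers of the 6 arrays. T and NK cell markers, of which 16 of 17 were higher (median 1.01), had a mean of 3.34 above controls on that array, against −0.70 on antagomir array 1 and 0.44 on antagomir array 3. Gzma, the gene of granzyme A, had a signal of 5852 there and of 46.5 to 85.6 on the others. H2-K1, a class I histocompatibility gene, reached 126644, and the chemokine gene Cxcl10 2290, all 3 genes chosen after their values were seen. Adjusted over the list alone, and over all genes, 0 markers passed by limma, and 1 had an unadjusted p under 0.05. The list rose by camera (adjusted p = 0.0297), with adjusted p = 0.734 with an estimated correlation. Without antagomir array 2 its median was −0.16 (adjusted p = 0.332), and without control array 3 the call was lost too (median 1.00, adjusted p = 0.171), as it was with array weights (0.15 and 0.907) and by the equal-variance test (adjusted p = 0.0968). Without antagomir array 1 its median was 1.93. Other lists were high on antagomir array 2 too, with means above controls of 2.24 for red blood cells and platelets, 1.69 for neutrophils and mast cells, 0.97 for cytokines, 0.93 for epicardial and 0.70 for macrophage markers, while B and plasma cell markers, at 0.36, equalled control array 3. Interferon response genes, with a mean of 1.65 on that array, had a median of 0.12 (camera adjusted p = 0.830) and of −0.50 without antagomir array 2 (adjusted p = 6.95e-12). Over its other alternatives the adjusted p ran from 0.0491 to 0.955, with a negative median for array weights alone (−0.10).

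Atrial genes were high on antagomir arrays 2 and 3, and the labels do not say which part of the heart was taken. The 17 atrial markers had means of 1.54 and 2.01 above controls there, against −0.21 on antagomir array 1 and 0.53 on control array 3 (median of the list 0.57, from 0.19 without antagomir array 2 to 0.61 without control array 1, camera adjusted p = 0.294). Myl7, the atrial myosin light chain, chosen after its values were seen, had signals of 14.7 to 461 in controls and of 47.0, 4031 and 14938 on antagomir arrays 1, 2 and 3, and Myl4, also so chosen, of 1148 to 5639 and of 1656, 41377 and 108011. Adipocyte and brown fat markers were higher for 16 of 22 (median 0.33), with means of 1.20 and 1.27 on antagomir arrays 2 and 3 and 0.88 on control array 3. Among them Lipe, hormone-sensitive lipase, had a log2 fold change of 0.84 (SE 0.33) and Dio2, a deiodinase that other cells make too, of −3.24 (SE 0.78). All 5 thymus markers tested were higher (median 0.65, 1 past the test adjusted over the list alone), with Ccr9 at 0.79 (SE 0.30). Cell cycle genes were lower for 28 of 36 (median −0.36), with Prc1 at −1.60 (SE 0.76) and Cdk1 at −1.68 (SE 0.83). These lists passed camera, with adjusted p = 0.0273 for adipocyte, 0.0129 for thymus and 0.00137 for cell cycle, and adjusted p = 0.625, 0.369 and 0.660 with an estimated correlation. Adjusted over the list alone 0 adipocyte and 0 cell cycle genes passed, and over all genes 0 of any of these lists by limma, with 5, 2 and 0 at an unadjusted p under 0.05. The adipocyte call was lost without antagomir array 2 (median 0.39, adjusted p = 0.265) or control array 1 (0.41 and 0.134), above background on all 6 arrays (0.27 and 0.308) and with no filter (0.51 and 0.20). It was also lost with a mean signal of at least 200 (0.32 and 0.0535) and by the equal-variance test (adjusted p = 0.0773). The adipocyte median was 0.54 without control array 3, and 0.14 with the slide row as a block, which leaves control array 3 alone against the antagomir arrays. The thymus call was lost without antagomir array 2 (0.60 and 0.168), with quantile scaling (0.20 and 0.248), with the authors' table (0.20 and 0.249), with normexp (0.11 and 0.263), with no filter (adjusted p = 0.0738) and with a variance trend (adjusted p = 0.0662). The cell cycle call was lost without antagomir array 1 (−0.078 and 0.219), antagomir array 3 (−0.32 and 0.146) or control array 2 (−0.085 and 0.185). Its median was −0.58 without control array 3, −0.72 without antagomir array 2 and −0.0089 with the slide row as a block.

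The remaining lists did not pass camera with these settings. Their medians and adjusted p were 0.70 and 0.0559 for conduction and pacemaker markers, 0.12 and 0.506 for glycolysis and hypoxia, −0.23 and 0.0978 for B and plasma cells, 1.13 and 0.107 for neutrophils and mast cells, and −0.022 and 0.113 for epicardial and mesothelial markers. They were 0.22 and 0.766 for skeletal muscle, 0.16 and 0.830 for lung and airway epithelium, −0.18 and 0.135 for Schwann cells and neurons, and 0.60 and 0.551 for red blood cells and platelets. For handling and stress they were 0.014 and 0.174 for immediate early genes, 0.027 and 0.599 for the unfolded protein response, 0.08 and 0.830 for oxidative stress, −0.07 and 0.187 for apoptosis and p53 targets, and 0.10 and 0.0978 for cytosolic ribosomal proteins. The B and plasma cell median ran from −0.68 without antagomir array 2 to −0.0019 without control array 3, and the neutrophil median from 0.42 without antagomir array 2 to 1.43 without control array 1. With quantile scaling the medians of glycolysis, lung, immediate early, unfolded protein and ribosomal genes turned negative. Over the other settings, conduction markers passed in 8 (adjusted p down to 0.00561), B and plasma cells in 5 (down to 0.00096), ribosomal proteins in 5 (down to 0.000669), epicardial markers in 4 (down to 2.59e-05), neutrophils in 3 (down to 0.00189), immediate early genes in 4 (down to 5.28e-05, with a positive median in 2 and a negative in 2), Schwann cells in 1 (adjusted p = 0.0453) and apoptosis in 1 (adjusted p = 0.0161). The counts for B and plasma cells, neutrophils and immediate early genes include the slide row block, which leaves control array 3 alone, and the lowest B cell p is from it. Red blood cells passed without antagomir array 1 (median 1.48, adjusted p = 5.36e-08), and so did atrial markers (median 0.36, adjusted p = 0.0157), which passed with normexp too. Adjusted over the list alone, 3 conduction markers passed, 2 higher and 1 lower, as did 1 B cell marker, lower, and 2 skeletal muscle markers, 1 each way. Of 3 sex-linked genes tested 0 passed over the list alone or over all genes by limma, and 0 had an unadjusted p under 0.05.

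The lower matrix genes may come from more than 1 source. The fall did not rest on antagomir array 3, since without that array the median of the list was −1.76. The raised low end of that array adds signal, which would not lower these genes, so leaving it out was a weak test of that source. A lower share of every non-myocyte cell type would lower endothelial, smooth muscle and macrophage markers alike, but the 77 such markers lay 1.5 (SE 0.25) above the matrix list, with a median of −0.14. That SE comes from resampling genes, which are not independent replicates, and leaves out the spread between arrays. Less scar or a smaller infarct in the sampled piece of heart stays open: across genes, differences between control hearts and between the groups correlated between −0.36 and −0.17 over 3 pairings of control arrays, and the bound for a clear answer was set after these values were seen. A direct effect of the antagomir on fibroblasts was not tested and cannot be separated from that here.

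Copies of the lymphatic chemokine gene Ccl21 on chromosome 4 were lower, with small spread, were chosen after their values were seen, and are so nearly identical that the probes may measure any of them. Gm1987 had a log2 fold change of −1.40 (SE 0.14, limma adjusted p = 0.168) and Gm13304 of −1.32 (SE 0.14, adjusted p = 0.196), and both passed with a variance trend and robust moderation (adjusted p = 0.0336). A copy number difference of the cluster between the mice stays open. The 15 genes next to them by the gene table had a median of 0.11 (SE 0.10, from −0.80 to 0.39), above the bound written beforehand. But that bound was wrong, since the set holds genes outside the repeated stretch, which need not share its copy number. The array design puts the probes of Dhrsx and Gm3893 on sequence not placed along a chromosome and gives Cd99 no position, so these may not be neighbours. Less lymphatic endothelium in the sampled tissue stays open: its 11 markers, 4 of them in another list too, had a median of −0.78 (SE 0.28, from −1.38 to 0.23 for Prox1), and 10 were lower. That median is past the bound of −0.7 written beforehand, and the need to clear it by the standard error was added after the value was seen. The SEs of the medians of neighbours and lymphatic markers come from resampling genes and leave out the spread between arrays.

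The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 3 genes at an adjusted p under 0.05, as many as in 1 of the 10 splits, itself, and the highest other gave 1. It gave 1658 genes at an unadjusted p under 0.05, and 2 of the 10 splits gave as many, the highest other 1918, where control arrays 1 and 2 and antagomir array 2 stood against the rest. It gave 22 lists past camera, reached by 1 of the 10 splits, and the others gave 12 to 21. Many lists thus passed camera with the preset correlation in any split. The median size of the matrix shift was 1.63, and the highest other 1.24.

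Between the groups, 42 probes were dim on all controls and bright on all antagomir arrays, and 171 were the reverse. The count depends on the side of antagomir array 3, with its raised low end. Other groupings of 3 arrays against 3 gave 9 to 66 with that array among the dim ones, all below 171. They gave 40 to 256 with it among the bright ones, where 42 is near the lowest.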
